A study of Drosophila melanogaster with 21 samples.

How the data were processed

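RNA of 21 cultures of DL1, a Drosophila melanogaster cell line, was measured in 7 groups of 3. In the knockdown experiment (12 samples), cells were bathed for 60 min with 20 µg of double-stranded RNA against pum, Not1, Pop2 or, as the control, the bacterial LacZ gene, and were harvested after 48 h, per the labels. In the knockout experiment (9 samples), 2 clonal isolates with a knockout of pum were set against the parental wild-type (WT) line. The labels call the samples biological replicates. The 3 samples of each knockout group are samples of 1 isolate, so their spread does not include differences between isolates. Libraries were made from poly(A)-selected RNA by ClickSeq, per the labels' protocols. In ClickSeq, reverse transcription is stopped at random by azido-nucleotides and the adapter is joined by click chemistry, so no fragmentation step is needed.

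The submitters' processing notes name fastp 0.14.1 (read trimming), HISAT2 2.1.0 (alignment), UMI-tools 1.0.1 (molecular identifiers), featureCounts (read counting, version not given in the sources used here), DESeq2 1.23.110 and the genome build dm6, without saying how each was set. Whether strand was used in counting is not given in the sources used here, so values of overlapping genes, of antisense RNAs and of near-identical paralogs (RpS19a and RpS19b, the GstD and GstE clusters, the Hsp70 copies) may share reads. The authors deposited 2 tables, 1 per experiment, normalized separately. The deposited signal columns are group means of normalized counts, that is, counts divided by a size factor per library and averaged over the group, per the file headers. The deposited log2 columns are the authors' log2 fold changes against the control group with their standard errors. A fold is 2 to the power of that fitted value and can depart from the ratio of the deposited means. The deposited p-value columns are the p-values of the authors' DESeq2 two-sided Wald test and their adjusted values. Lines without a gene (7 in each table) held 0.045% of the normalized counts of the RNAi table and 0.067% of the knockout table and stayed out of every count.

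Choices made before the data were examined were the comparisons, the adjusted p threshold of 0.05, the 28 gene lists, the rule for named genes and a set of alternatives. That plan used count tests if counts were given and the deposited values if only tables of comparisons were given. The second case applied. Every fold change, standard error and per-gene p in the results is therefore the authors' own, and a gene is called changed where the authors' adjusted p is below 0.05. A gene counts as tested where the table gives an adjusted p (8596 genes for Pum RNAi, 9051 for Not1 RNAi and Pop2 RNAi, 10156 and 9925 for clones 1 and 2). Differences between comparisons were tested as the difference of the 2 log2 fold changes over the root of the summed squared standard errors, with a Benjamini-Hochberg adjusted p. That test overstates the error because both comparisons share their controls. Overlaps of calls were tested with a one-sided Fisher's exact test per direction over genes tested in both, and its p-value is not printed where comparisons share controls, which it leaves out. Correlations are across genes with a mean of at least 50 normalized counts, and genes are not independent replicates.

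Gene lists were tested with limma's camera on the Wald statistics with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera compares a list with all other genes. Camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance in 1 direction, were run on reconstructed reads. The lists, written from general knowledge, are: the targets; CCR4-NOT subunits; other decay factors; RNA-binding and microRNA-pathway repressors; earlier reported Pumilio targets; cytosolic ribosomal proteins; mitochondrial ribosomal proteins; oxidative phosphorylation; proteasome; glycolysis; cell cycle; antimicrobial and peptidoglycan recognition; JAK/STAT and JNK response; apoptosis and p53; heat shock; endoplasmic reticulum and integrated stress; glutathione transferase and oxidative stress; RNA interference and antiviral; ribosome biogenesis; ecdysone response; lipid synthesis and storage; Ras/MAPK; Notch, Wnt and Hippo; and markers of hemocytes, germline and gonad, neurons, muscle and epithelium. Counts adjusted over the list alone are given beside counts over all genes for part of the lists. Where they are not printed, they can differ from the count over all genes. The rule for named genes took, per comparison, pum, Not1 and Pop2, the 8 largest rises and 8 largest falls among called genes with a mean of at least 20 normalized counts and no overlap between treated and control libraries, where libraries could be resolved, and up to 4 members of each list with the smallest p. For the clones both had to pass in the same direction. Among the largest changes, genes known only by a number were passed over for the next with a symbol (2 rises and 2 falls for Pum RNAi, 5 and 4 for Not1 RNAi, 4 and 1 for Pop2 RNAi, 10 and 10 for the clones).

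The tables hold no value per library. Because the means are printed to 15 digits, the whole-number read counts and size factors of the 3 libraries behind a mean could be solved for. This is a reconstruction, not a deposited value, and it was chosen after the tables were seen. Tested on data simulated from the LacZ RNAi means alone, it resolved 17533 of 17562 genes with 0 wrong. That count takes in genes at 0, which need no solving (10227 genes were above 0 in LacZ RNAi). On the real means the reconstruction resolved 99.9% of genes above 0 for LacZ RNAi, 98.0% for Pum RNAi, 99.7% for Not1 RNAi and Pop2 RNAi, 99.9% for WT, and 98.7% and 98.9% for the clones. The genes left unresolved are the most abundant ones and hold 39.5% of the normalized counts in Pum RNAi. Libraries are named A, B and C by falling size factor, since the reconstruction carries no replicate number. The reconstructed reads served only for depth, for values per library and for alternatives: limma with a mean-variance trend on log2(normalized count + 1) over genes with a mean of at least 5 (7470 genes in the RNAi table, 7890 in the knockout table), other pseudocounts and filters, total library size, library quality weights, only the groups compared, leaving out each library, and leaving out the shallowest LacZ RNAi and Not1 RNAi libraries. Such fold changes are on the log2(value + 1) scale, which understates the change of low genes.

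Reads of 6502 genes were simulated on the model of Pum RNAi against LacZ RNAi, with 100 genes changed per fold size. When the third LacZ library was given excess spread, limma called 0% of genes changed 1.5-fold and 0% of those changed 2-fold. It called 20% and 87% without that library, and 21% and 92% with all libraries and no excess spread. The excess spread was set by hand as random noise per gene, not estimated from the data. Only the LacZ RNAi and Pum RNAi libraries were in this simulated fit. The reconstructed depth was 4071260 to 7001228 reads per LacZ RNAi library, 8414242 to 9803648 for Pum RNAi, 2387783 to 9531006 for Not1 RNAi, 6406934 to 8945926 for Pop2 RNAi, 5897680 to 8413503 for WT, 8796976 to 13794764 for clone 1 and 8189825 to 9890034 for clone 2. The median standard error of a log2 fold change was 0.29 for Pum RNAi, 0.31 for Not1 RNAi and 0.30 for Pop2 RNAi, against 0.16 for both clones. Shared controls were examined with 20 simulations of unchanged groups. Every simulated library, controls included, was drawn with the same spread per gene. A control library that stands apart was thus not modelled, and with no gene changed hardly any call could arise. The search for Pumilio response elements was not run, since no genome sequence was used here. Software was R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.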

Results

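DL1 cells were depleted of Pumilio (Pum), Not1 or Pop2 by RNA interference (RNAi), or carried a knockout of pum, and mRNA was measured by ClickSeq, an RNA-seq method without fragmentation. Pumilio is an RNA-binding protein that represses mRNAs through elements in their 3' untranslated regions. Not1 is the scaffold and Pop2 a deadenylase subunit of CCR4-NOT, the main complex that shortens poly(A) tails. There were 3 samples each of LacZ RNAi (control), Pum RNAi, Not1 RNAi, Pop2 RNAi, wild type (WT) and Pum knockout (KO) clones 1 and 2. Reconstructed library depth ran from 2387783 reads (Not1 RNAi library C) to 13794764 reads (clone 1 library A). The shallowest LacZ RNAi library (4071260 reads) correlated with the other 2 of its group at 0.894 and 0.895 across genes, against 0.984 between those 2. Ribosomal protein genes lay 1.68 (log2, median of 44 genes) above the mean of the other 2 libraries in it. The shallowest Not1 RNAi library correlated at 0.924 and 0.925 with its group, against 0.994 between the others. Ribosomal protein genes in it lay 1.36 (log2) above the mean of the others. In the other 5 groups the lowest such correlation was 0.984.

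Each targeted gene fell in the samples named for its loss. In Pum RNAi, pum (FBgn0003165, chromosome 3R, 9066343 to 9237682 in dm6) fell 3.23-fold, from a mean of 1754.8 to 542.6 normalized counts (log2 -1.69 ± 0.39, standard error, SE, adjusted p = 0.00575), in the authors' deposited table. In Not1 RNAi, the authors' deposited table gave a 9.64-fold fall of Not1 (FBgn0085436, chromosome 2R, 9566146 to 9579007), from 16829.7 to 1748.4 (log2 -3.27 ± 0.18, adjusted p = 4.1e-72). In Pop2 RNAi, Pop2 (FBgn0036239, chromosome 3L, 11998398 to 12002915) fell 20.2-fold, from 575.9 to 28.7 (log2 -4.34 ± 0.32, adjusted p = 1.6e-40), in the authors' deposited table. For clone 1 the authors' deposited table gave pum a fall of 2.93-fold, from 3029.3 to 1035.6 (log2 -1.55 ± 0.07, adjusted p = 5.78e-103). For clone 2 the fall of pum in the authors' deposited table was 1.43-fold, to 2121.9 (log2 -0.51 ± 0.07, adjusted p = 1.47e-12). The deleted part of pum is not given in the sources used here, so reads outside it check nothing about the knockout itself. Folds here and below are the authors' fitted values, which can depart from the ratio of the group means printed beside them.

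The targets also moved outside their own knockdowns. In the authors' deposited table, pum rose 2.68-fold in Not1 RNAi (log2 1.42 ± 0.39, adjusted p = 0.000771). That rise of pum was 0.83 (log2) by limma, another test, without the shallowest LacZ RNAi and Not1 RNAi libraries. Library C of Not1 RNAi held 8624 normalized counts of pum against 2927 and 2570 in the others. Not1 rose 1.68-fold in Pop2 RNAi (log2 0.75 ± 0.18, adjusted p = 0.00014) in the authors' deposited table. Pop2 rose 1.49-fold in clone 1 and 1.59-fold in clone 2 in the authors' deposited table (log2 0.57 ± 0.08 and 0.66 ± 0.08).

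**Figure D1:**
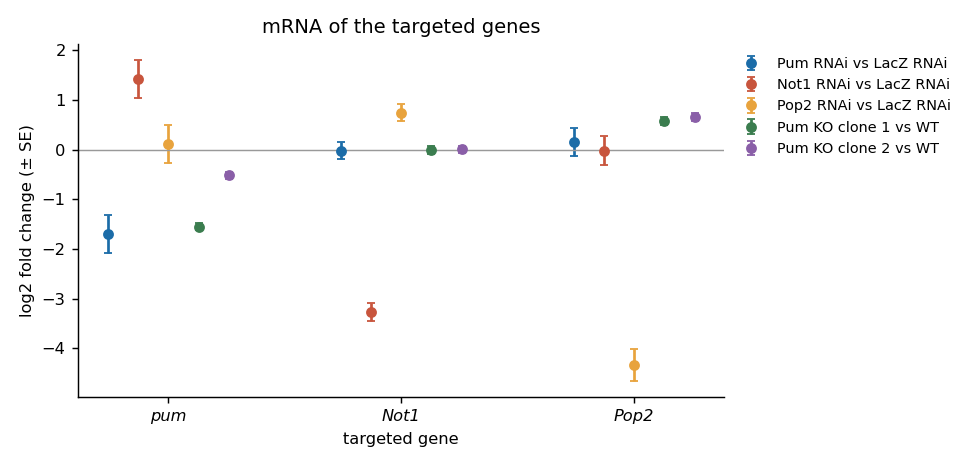
Log2 fold change of pum, Not1 and Pop2 (vertical axis, points, with the standard error as bars) in each of the 5 comparisons (colours), from the authors' deposited table. Each knocked-down gene lies below 0 in its own knockdown (pum -1.69, Not1 -3.27, Pop2 -4.34), and pum lies at -1.55 and -0.51 in the clones.

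Pum RNAi against LacZ RNAi asked which mRNAs change when Pumilio is depleted. By the authors' test 44 genes rose and 19 fell among 8596 tested, and 23 of the 63 changed at least 2-fold. The count moved with the libraries: on the reconstructed reads limma called 1 gene with all of them, 585 without the shallowest LacZ RNAi and Not1 RNAi libraries and 1911 with library quality weights. Among called genes with a symbol, the largest rise was that of dec, an eggshell protein gene, with a fitted rise of 3.45-fold (log2 1.79 ± 0.41, adjusted p = 0.0057) and group means of 16.7 and 62.3 normalized counts in the authors' deposited table. bib (FBgn0000180, chromosome 2L, 9984645 to 9995538), which encodes a membrane protein of the aquaporin family, rose 3.27-fold from 38.8 to 133.9 (log2 1.71 ± 0.27, adjusted p = 6e-07) in the authors' deposited table. Nna1, a carboxypeptidase gene, Kif3C, a kinesin, and MP1, a protease of the melanization cascade, rose 2.84-, 2.59- and 2.40-fold in the authors' deposited table. RnrS, the small subunit of ribonucleotide reductase, amx, a Notch pathway gene, and ORMDL, a regulator of sphingolipid synthesis, rose 2.32-, 2.32- and 2.31-fold in the authors' deposited table. After pum itself, the largest fall among called genes with a symbol was that of Men, malic enzyme, 3.20-fold from 2447.5 to 763.1 (log2 -1.68 ± 0.22, adjusted p = 1.7e-10), in the authors' deposited table. klu, a zinc finger transcription factor gene, fell 2.94-fold, Msp300, a nesprin, 2.25-fold, and Muc14A, a mucin, 1.97-fold in the authors' deposited table. Cand1, a regulator of cullin ubiquitin ligases, LeuRS, leucyl-tRNA synthetase, and Sf3b1, a splicing factor, fell 1.87-, 1.68- and 1.64-fold in the authors' deposited table.

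Few members of the lists passed the authors' test in Pum RNAi. RnrS was the 1 of 31 cell cycle genes called (2 higher and 1 lower adjusted over the list alone). Raf, the kinase of the Ras/MAPK pathway, was the 1 of 13 of its list, with a log2 rise of 0.67 ± 0.17 (adjusted p = 0.0293) in the authors' deposited table. The Wnt receptor gene fz was the 1 of 19 Notch, Wnt and Hippo genes, up 2.07-fold (log2 1.05 ± 0.25, adjusted p = 0.0102) in the authors' deposited table. Of 12 glycolysis enzymes, PyK, pyruvate kinase, fell by 0.42 on the log2 scale (SE 0.10, adjusted p = 0.00575) in the authors' deposited table, and it was the 1 called adjusted over the list alone as well. Of the 14 earlier reported Pumilio targets 0 were called by the authors' DESeq2 test (772 of all genes had an unadjusted p below 0.05) and 0 by limma with all libraries, which called 1 gene in all. By limma 1 was higher and 2 were lower of 13 without the shallowest LacZ RNAi and Not1 RNAi libraries. Egfr, the epidermal growth factor receptor, had the smallest p of them (log2 0.77 ± 0.30, adjusted p = 0.31) in the authors' deposited table.

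Camera placed 8 lists apart from other genes in Pum RNAi. Cytosolic ribosomal protein genes had a median of -0.55 (83 measured, 0 called, also 0 adjusted over the list alone; adjusted p = 7.73e-09, and adjusted p = 0.862 with an estimated correlation). Glycolysis enzymes had a median of -0.28 (adjusted p = 2.43e-04, and adjusted p = 0.580 with an estimated correlation). Mitochondrial ribosomal proteins (71 measured, median -0.22, adjusted p = 0.00487), decay factors (27, -0.20, 0.00810), oxidative phosphorylation (61, -0.18, 0.00810), ribosome biogenesis (12, -0.30, 0.00925) and endoplasmic reticulum and integrated stress genes (11, -0.28, 0.0321) were also low, with 0 called in each. Decay factors had 1 lower adjusted over the list alone, the helicase gene tst (log2 -0.34 ± 0.10, adjusted p = 0.079 over all genes in the authors' deposited table). Ras/MAPK genes were high (median 0.27, adjusted p = 0.0182). The mitochondrial ribosomal and oxidative phosphorylation lists had an adjusted p = 0.862 with an estimated correlation, ribosome biogenesis 0.701, and the decay, stress and Ras/MAPK lists 0.580. Camera with an estimated correlation thus called 0 of 26 lists (2 at an unadjusted p below 0.05), and fry called 0 (3 at an unadjusted p below 0.05). In the shallowest LacZ RNAi library ribosomal protein genes are the ones that lay 1.68 (log2) above the mean of the others of its group. Without that library and its Not1 RNAi counterpart the median of the 44 reconstructed members went from -0.38 to 0.13 (camera adjusted p = 0.0278 for higher). Without the same libraries oxidative phosphorylation also passed in the opposite direction (median -0.15 with all libraries and 0.09 without these, adjusted p = 0.0278 for higher). The mitochondrial ribosomal (median 0.07, adjusted p = 0.349), decay (0.307), ribosome biogenesis (0.307), stress (0.113, and 0.172 on the reconstructed reads of all libraries) and Ras/MAPK (0.281) lists no longer passed, and glycolysis still did (median -0.22, adjusted p = 0.00272). With an estimated correlation and without these libraries the ribosomal protein and oxidative phosphorylation lists had an adjusted p = 0.847 and glycolysis 0.830. Scaling by total library size took the median of all genes from 0.02 to 0.30 in Pum RNAi. It left ribosomal protein genes at -0.09 and ribosome biogenesis at -0.01 and took the decay, mitochondrial ribosomal, oxidative phosphorylation, glycolysis and stress medians above 0 (0.10, 0.10, 0.13, 0.02 and 0.13). Relative to the median of all genes they were -0.39, -0.31, -0.20, -0.20, -0.17, -0.28 and -0.17.

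The other lists did not pass camera on the deposited values in Pum RNAi. These were CCR4-NOT subunits (9 measured), repressors (9), proteasome (32), antimicrobial and peptidoglycan recognition (10), JAK/STAT and JNK (14), apoptosis (12), heat shock (10), glutathione transferase and oxidative stress (18), RNA interference (9), ecdysone (10) and lipid genes (12), and markers of hemocytes (13), germline and gonad (8), neurons (7), muscle (6) and epithelium (10). The authors' DESeq2 test called 0 members in each of them, and so did limma with all libraries. On simulated reads of LacZ RNAi and Pum RNAi alone, with excess spread set by hand in 1 LacZ library, limma called 0% of genes changed 2-fold. Without the shallowest LacZ RNAi and Not1 RNAi libraries proteasome subunits passed camera as higher (4 higher and 0 lower of 31, median 0.13, adjusted p = 0.00338) and repressors as lower (1 lower of 7, median -0.24, adjusted p = 0.0278). Neither passed there with an estimated correlation (adjusted p = 0.830 for both) or by fry (0.123 and 0.155). Higher and lower members were then 1 and 2 of the antimicrobial, 1 and 1 of the JAK/STAT and JNK, 0 and 1 of the heat shock, 0 and 2 of the ecdysone, 0 and 1 of the lipid and 2 and 0 of the hemocyte list, with 0 called in the rest. Median, mean and camera differed in sign for CCR4-NOT subunits and for hemocyte and epithelial markers. Adjusted over the list alone, 1 rose and 1 fell of the antimicrobial list (CecC 0.96 ± 0.36 and Rel -0.34 ± 0.13 on the log2 scale in the authors' deposited table) and 1 hemocyte marker rose (lz, listed at 0 in LacZ RNAi and 3.8 in Pum RNAi). The count of changed genes moved with the test and the libraries. On the reconstructed reads, limma called 1 gene with all libraries (604 at an unadjusted p below 0.05) and 585 (303 higher, 282 lower) without the shallowest LacZ RNAi and Not1 RNAi libraries. It called 0 to 20 when 1 library at a time was left out (20 without Not1 RNAi library C, 2 without LacZ RNAi library C). pum had a log2 fold change of -1.67 in limma with all libraries and was not called there.

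Not1 RNAi against LacZ RNAi asked which mRNAs depend on the CCR4-NOT scaffold. It changed the transcriptome broadly, with 2328 genes higher and 2194 lower among 9051 tested, 2959 of them at least 2-fold. Counts were scaled by a size factor per library, so rises and falls here and in Pop2 RNAi are relative to other genes. A shift of all mRNAs together would not show. The RNA was poly(A)-selected, and CCR4-NOT shortens poly(A) tails. Whether tail length altered the capture of an mRNA was not tested, so a call need not be a change in mRNA amount. The tyrosine kinase receptor gene Tie rose 159-fold, from 12.2 to 1988 normalized counts (log2 7.31 ± 0.32), in the authors' deposited table. There too, sano, a planar polarity gene, rose 151-fold, from 44.9 to 6626.9 (log2 7.24 ± 0.38), and hoe1 218-fold, from 5.2 to 1183.5 (log2 7.77 ± 0.52), in the authors' deposited table. NimA, of the Nimrod receptor family, went from 0.3 to 511.6 normalized counts, sr, a transcription factor gene of tendon cells, from 1.0 to 474.4, CCAP-R, a neuropeptide receptor gene, from 2.8 to 378.8, and Tsp5D, a tetraspanin, from 0.7 to 77.8 in the authors' deposited table. The transcription factor gene Blimp-1 was listed at 0 in LacZ RNAi and at 70.6 in Not1 RNAi in the authors' deposited table. klu, with group means of 115.2 and 4.1, had a fitted fall of 43.3-fold (log2 -5.44 ± 0.64), and RpS19b, a ribosomal protein paralog with means of 131.9 and 4.2, of 22.9-fold (log2 -4.52 ± 0.43) in the authors' deposited table. Muc14A fell 12.5-fold, the phosphate transporter gene NaPi-III 11.6-fold, Hacd2, of fatty acid elongation, 11.5-fold, spermidine synthase SpdS 11.3-fold and the lysosomal mannosidase gene LManI 11.1-fold in the authors' deposited table. GNBP2, a pattern recognition gene, had a log2 fold change of -3.45 ± 0.36 in the authors' deposited table.

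Camera placed glycolysis enzymes, cytosolic ribosomal proteins, oxidative phosphorylation subunits and ribosome biogenesis genes lower than other genes in Not1 RNAi. Of 12 glycolysis enzymes 11 fell and 0 rose (the same numbers adjusted over the list alone; median -1.61, adjusted p = 1.57e-12, and adjusted p = 0.172 with an estimated correlation). The log2 fold changes were -2.20 ± 0.18 for Eno, -1.93 ± 0.13 for Gapdh2, -1.71 ± 0.12 for Ald1 and -1.24 ± 0.10 for PyK in the authors' deposited table. Cytosolic ribosomal protein genes were lower in 48 of 83 (58 adjusted over the list alone; median -1.10, adjusted p = 1.06e-06, and adjusted p = 0.689 with an estimated correlation), among them RpS3A (log2 -1.66 ± 0.16) and RpS19a (-1.48 ± 0.12) in the authors' deposited table. Ribosomal protein genes stood high in the shallowest library of both groups, and without those libraries the median of the 44 reconstructed members was -0.98, against -1.06 with all libraries. The median of oxidative phosphorylation, described next, was -0.63 by limma with all libraries and -0.28 without those libraries (adjusted p = 0.0186, and adjusted p = 0.775 with an estimated correlation). Oxidative phosphorylation subunits had 33 lower and 1 higher of 62 (also adjusted over the list alone; median -0.66, adjusted p = 5.12e-05, and adjusted p = 0.689 with an estimated correlation), with ATPsynC at -1.70 ± 0.17 and ATPsynbeta at -1.59 ± 0.15 (log2) in the authors' deposited table. Ribosome biogenesis genes had 8 of 12 lower (8 adjusted over the list alone; median -0.86, adjusted p = 7.11e-04, and adjusted p = 0.643 with an estimated correlation). Nopp140 changed by -2.33 ± 0.17, nop5 by -2.27 ± 0.26 and Nop60B, the pseudouridine synthase, by -2.12 ± 0.22 on the log2 scale in the authors' deposited table.

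Camera placed JAK/STAT and JNK response genes and Ras/MAPK genes higher in Not1 RNAi, and apoptosis genes went both ways. JAK/STAT and JNK response genes had 10 higher and 2 lower of 14 (also adjusted over the list alone; median 1.49, adjusted p = 0.00136, and adjusted p = 0.332 with an estimated correlation). The tumour necrosis factor gene egr rose 2.64 ± 0.34, the metalloprotease gene Mmp1 1.92 ± 0.19 and Jra, the fly Jun, 1.86 ± 0.17 on the log2 scale in the authors' deposited table. Ras/MAPK genes had 10 higher and 1 lower of 13 (also adjusted over the list alone; median 0.82, adjusted p = 0.00737, and adjusted p = 0.630 with an estimated correlation), led by Egfr (log2 2.53 ± 0.30) and the repressor gene aop (2.33 ± 0.27) in the authors' deposited table. The cell death inducers rpr and hid rose 36.9-fold and 10.1-fold in the authors' deposited table, from 12.4 to 482 and from 52.2 to 539.7 normalized counts. Of 12 apoptosis and p53 genes 5 rose and 5 fell (adjusted p = 0.665), and Xrp1 (log2 -1.36 ± 0.15) and Gadd45 (-2.17 ± 0.25) were among those that fell in the authors' deposited table. Of the 14 earlier reported Pumilio targets 5 rose and 2 fell (5 and 3 adjusted over the list alone; adjusted p = 0.341), hid, Egfr and the Ras activator gene Sos (1.52 ± 0.22) among the rises and cyclin B, CycB (-1.43 ± 0.14), among the falls in the authors' deposited table.

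Within the decay machinery, Not1 RNAi moved other genes besides its target. Of 9 CCR4-NOT subunits 1 rose and 2 fell (adjusted p = 0.341): Rga, the fly Not2, rose 3.88-fold (SE 0.32 on the log2 scale) and Rcd-1 fell by 0.38 on the log2 scale (SE 0.13, adjusted p = 0.012), with Not1, in the authors' deposited table. Of 27 decay factors 4 rose and 12 fell (5 and 12 adjusted over the list alone; adjusted p = 0.249), with the helicase gene me31B at -1.78 ± 0.23 and the exonuclease gene Rat1 at 1.18 ± 0.15 (log2) in the authors' deposited table. Repressors had 5 higher and 0 lower of 10 (adjusted p = 0.396), among them AGO1 (log2 1.43 ± 0.41) and gw (0.60 ± 0.17) of the microRNA pathway in the authors' deposited table.

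The remaining lists did not pass camera on the deposited values in Not1 RNAi. Proteasome subunits had 13 higher and 1 lower of 32 (12 and 1 adjusted over the list alone; adjusted p = 0.0524), with Rpt6 at 1.29 ± 0.20 (log2) in the authors' deposited table. On the reconstructed reads 3 of these lists did pass, proteasome subunits as higher (adjusted p = 0.0232) and mitochondrial ribosomal proteins (0.0239) and glutathione transferase and oxidative stress genes (0.0464) as lower. With an estimated correlation none of them passed (adjusted p = 0.689, 0.733 and 0.332). Without the shallowest LacZ RNAi and Not1 RNAi libraries proteasome subunits passed, with 27 higher and 1 lower of 31 (median 0.68, adjusted p = 1.52e-05, and adjusted p = 0.618 with an estimated correlation). Mitochondrial ribosomal proteins (median -0.39 with all libraries and -0.13 without these, adjusted p = 0.468) and glutathione transferase and oxidative stress genes (adjusted p = 0.0944) did not pass there. The counts were 1 higher and 25 lower of 72 mitochondrial ribosomal proteins (0 and 19 adjusted over the list alone; adjusted p = 0.0754), 8 and 13 of 31 cell cycle genes, 3 and 8 of 18 glutathione transferase and oxidative stress genes and 1 and 3 of 9 RNA interference genes. There were 5 and 0 of 10 ecdysone genes, 3 and 3 of 12 lipid genes, 2 and 3 of 11 endoplasmic reticulum and integrated stress genes, 4 and 2 of 12 heat shock genes, 2 and 2 of 13 antimicrobial genes and 6 and 2 of 19 Notch, Wnt and Hippo genes. Markers had 5 higher and 2 lower of 13 for hemocytes, 3 and 2 of 9 for germline and gonad, 3 and 0 of 7 for neurons, 0 and 0 of 8 for muscle (authors' DESeq2 test, with 0 of 2 by limma and 1 higher without the shallowest libraries) and 6 and 1 of 10 for epithelium. Desat1, the fatty acid desaturase, fell from 3197.1 to 789.3 normalized counts, the phagocytic receptor gene eater changed by -2.50 ± 0.23 and Syn, synapsin, by 3.00 ± 0.41 on the log2 scale in the authors' deposited table. With only the LacZ RNAi and Not1 RNAi libraries in the fit, limma called 2717 genes, against 4036 with all RNAi libraries.

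Pop2 RNAi against LacZ RNAi asked the same of the deadenylase subunit. Here 1705 genes rose and 1822 fell among 9051 tested, 1902 of them at least 2-fold. The integrin gene mew rose 74.2-fold, from 12.7 to 902.9 normalized counts (log2 6.21 ± 0.30), in the authors' deposited table. The transcription factor gene ab rose 68.7-fold, from 3.8 to 259 (log2 6.10 ± 0.62), and hoe1 went from 5.2 to 542.8 (log2 6.65 ± 0.52) in the authors' deposited table. sr went from 1.0 to 391, NimA from 0.3 to 103.8, CCAP-R from 2.8 to 172.4 and Tsp5D from 0.7 to 69.7 normalized counts, and Blimp-1 was listed at 0 and at 21.6, in the authors' deposited table. klu fell 28.7-fold (log2 -4.84 ± 0.50), RpS19b 12.4-fold (-3.64 ± 0.32) and GNBP2 10.2-fold (-3.35 ± 0.33) in the authors' deposited table. The glial glycoprotein gene ana fell 10.3-fold, the transporter gene MFS14 8.72-fold, Muc14A 8.56-fold and Glt, glutactin of the basement membrane, from 2627.8 to 328.1 normalized counts in the authors' deposited table.

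Ribosomal protein genes fell in Pop2 RNAi, 80 of 83 (also 80 adjusted over the list alone; median -1.61, adjusted p = 3.67e-15, and adjusted p = 0.726 with an estimated correlation). RpS3A had a log2 fold change of -1.31 ± 0.15 and RpS19a of -1.25 ± 0.12 in the authors' deposited table. The median of the 44 reconstructed members was -1.33 with all libraries and -0.84 without the shallowest LacZ RNAi and Not1 RNAi libraries. Glycolysis enzymes were lower in 11 of 12 (also adjusted over the list alone; median -1.22, adjusted p = 2.45e-12, and adjusted p = 0.159 with an estimated correlation), with Tpi at -1.81 ± 0.18, Pfk at -1.67 ± 0.14 and Gapdh2 at -1.54 ± 0.13 (log2) in the authors' deposited table. Oxidative phosphorylation had 29 lower and 0 higher of 62 (also adjusted over the list alone; adjusted p = 8.56e-06, and adjusted p = 0.726 with an estimated correlation), and mitochondrial ribosomal proteins 18 and 0 of 72 (11 adjusted over the list alone; adjusted p = 0.0156, and adjusted p = 0.732 with an estimated correlation). Ribosome biogenesis had 6 lower and 0 higher of 12 (also adjusted over the list alone; adjusted p = 0.0227, and adjusted p = 0.700 with an estimated correlation). Without the shallowest LacZ RNAi and Not1 RNAi libraries mitochondrial ribosomal proteins no longer passed (6 higher and 20 lower of 71, adjusted p = 0.263) and their median went from -0.43 by limma with all libraries to -0.13. That of oxidative phosphorylation went from -0.49 to -0.27 (adjusted p = 0.00205) and that of ribosome biogenesis from -0.67 to -0.44 (adjusted p = 0.0309), both with an adjusted p = 0.767 with an estimated correlation. Scaling by total library size took the median of all genes from 0.02 to 0.29 and the share of calls that were higher from 53.3% (1527 higher, 1337 lower) to 72.1% (1935 higher, 749 lower). Relative to that median the 5 lists were at -1.35, -1.23, -0.51, -0.45 and -0.69, in the order given, and their own medians stayed below 0 under that scaling.

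Ras/MAPK genes rose in 9 of 13 in Pop2 RNAi (also adjusted over the list alone; adjusted p = 0.00231, and adjusted p = 0.321 with an estimated correlation). JAK/STAT and JNK genes rose in 9 of 14, with 1 lower (also adjusted over the list alone; adjusted p = 0.0116, and adjusted p = 0.275 with an estimated correlation). Relative to the median of all genes under total library size these lists were at 0.65 and 0.98. aop rose 1.69 ± 0.27, Egfr 1.65 ± 0.30 and egr 1.97 ± 0.34 on the log2 scale in the authors' deposited table. rpr rose 8.81-fold in the authors' deposited table (log2 3.14 ± 0.38). The counts for lists that did not pass on the deposited values were 2 higher and 2 lower of 9 CCR4-NOT subunits, 2 and 7 of 27 decay factors, 1 and 0 of 10 repressors, 5 and 3 of 14 earlier reported Pumilio targets, 7 and 0 of 32 proteasome subunits and 10 and 5 of 31 cell cycle genes. Proteasome subunits did pass in Pop2 RNAi without the shallowest LacZ RNAi and Not1 RNAi libraries, with 22 higher and 0 lower of 31 (median 0.35, adjusted p = 0.00228, and adjusted p = 0.590 with an estimated correlation). Glutathione transferase and oxidative stress genes passed too, with 2 higher and 11 lower of 16 (median -0.81, adjusted p = 0.0309, and 0.0281 with all libraries). With an estimated correlation these had an adjusted p = 0.541, and 0.275 with all libraries. There were 5 and 4 of 12 apoptosis genes, 1 and 2 of 12 heat shock genes, 2 and 4 of 11 endoplasmic reticulum and integrated stress genes, 2 and 8 of 18 glutathione transferase and oxidative stress genes and 1 and 3 of 9 RNA interference genes. They were 0 and 3 of 13 antimicrobial, 5 and 0 of 10 ecdysone, 1 and 3 of 12 lipid and 4 and 1 of 19 Notch, Wnt and Hippo genes. Markers had 5 higher and 3 lower of 13 for hemocytes, 3 and 2 of 9 for germline and gonad, 2 and 0 of 7 for neurons, 0 and 0 of 8 for muscle (authors' DESeq2 test, with 0 of 2 by limma, and 1 and 1 without the shallowest libraries) and 5 and 1 of 10 for epithelium. Median, mean and camera differed in sign for the targets, the antimicrobial, RNA interference and Notch lists and the germline and epithelial markers. Rcd-1 changed by -1.11 ± 0.13, me31B by -1.24 ± 0.23 and the decapping enzyme gene DCP2 by -1.44 ± 0.28 on the log2 scale in the authors' deposited table. Limma called 2864 genes in Pop2 RNAi with all libraries, and with 1 left out between 2062 (without Pop2 RNAi library A) and 3732 (without Not1 RNAi library C). It called 4816 without the shallowest LacZ RNAi and Not1 RNAi libraries.

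**Figure D2:**
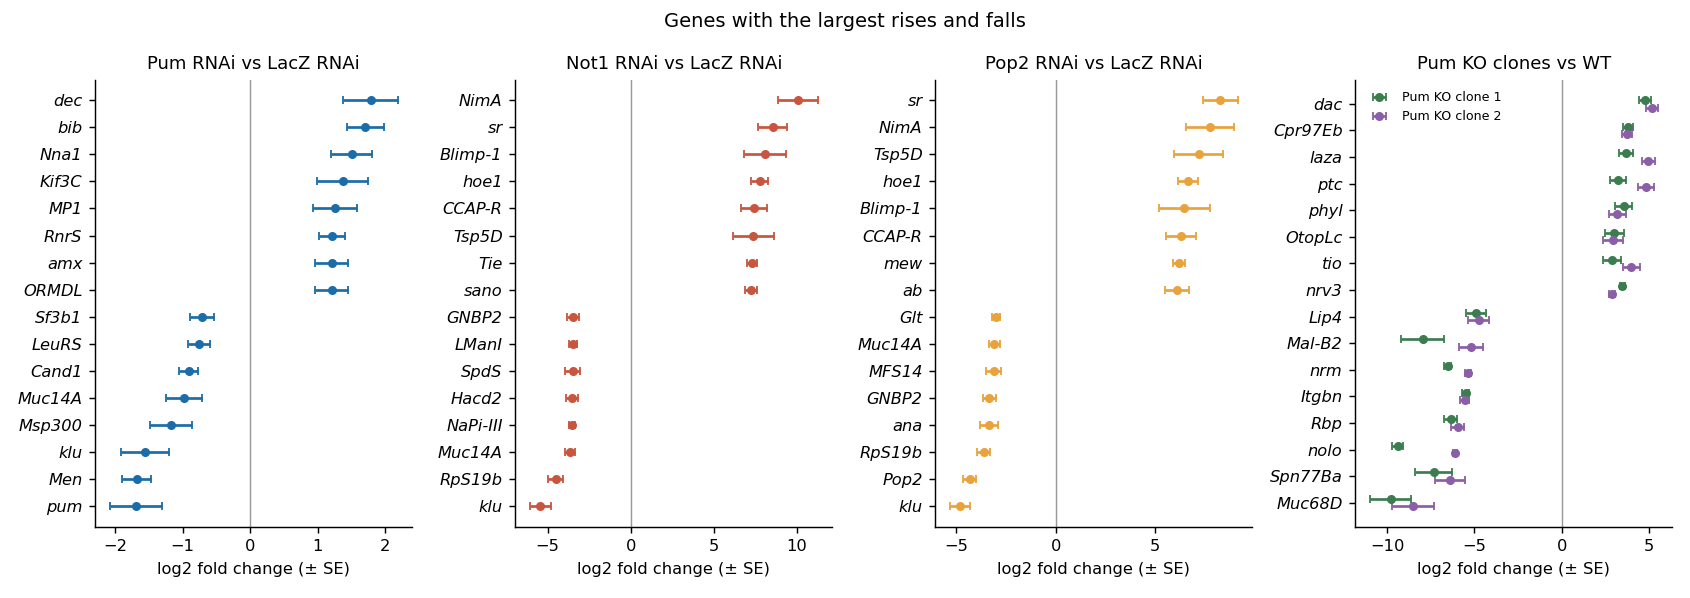
Log2 fold change (horizontal axis, points, with the standard error as bars) of the 8 largest rises and 8 largest falls per comparison among called genes with a symbol and a mean of at least 20 normalized counts, from the authors' deposited table. Scales differ between panels: dec reaches 1.79 in Pum RNAi, while Tie reaches 7.31 in Not1 RNAi and nolo -9.41 in clone 1.

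Loss of the scaffold and of the deadenylase changed largely the same genes in the same direction. Of the genes tested in both, 1548 rose and 1541 fell in Not1 RNAi and Pop2 RNAi, against 438.5 and 441.7 for independent lists, and 2 were called in opposite directions, against 881.9. bib was an example, up 96.8-fold in Not1 RNAi and 54.1-fold in Pop2 RNAi in the authors' deposited table. The fold changes correlated at r = 0.896 across 5847 genes (Spearman's rho 0.895). Simulated unchanged groups that shared a simulated control gave r = 0.503, where the reconstructed reads gave 0.910, and a covariance of 0.0747 against 1.30 observed. Their 0 shared calls follow from the setting, since no gene was changed. The LacZ RNAi library that stands apart was not modelled. A direct test found 115 genes that differed, 49 higher and 66 lower in Not1 RNAi. By limma the number was 419 with all libraries, 2289 without the shallowest LacZ RNAi and Not1 RNAi libraries, 1238 without LacZ RNAi library C alone and 61 without Pop2 RNAi library B. Part of the excess may come from the shared controls, which are too few to be split.

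Calls in Pum RNAi were set beside those in the CCR4-NOT knockdowns, which share the LacZ RNAi libraries as controls. Of the 44 rises in Pum RNAi, 21 also rose in Not1 RNAi (11.9 for independent lists) and 20 in Pop2 RNAi (8.72). Of the 19 falls, 12 also fell in Not1 RNAi (4.85) and 13 in Pop2 RNAi (4.01). The numbers for independent lists leave out the shared controls. Simulated unchanged groups gave 0 shared calls by limma, which follows from the setting, since no gene was changed. The LacZ RNAi library that stands apart was not modelled, so this does not measure the effect of the real controls. In the observed reads limma found 0 shared calls with Not1 RNAi and 1 with Pop2 RNAi. Opposite calls numbered 15 with Not1 RNAi (16.3 for independent lists) and 11 with Pop2 RNAi (13.1). In all 3 knockdowns 19 genes rose, among them dec, bib, Nna1, RnrS, amx, Raf and fz, and 12 fell, among them klu, Muc14A, Msp300, PyK and LeuRS. The direct tests found 2994 genes that differed between Pum RNAi and Not1 RNAi and 1670 between Pum RNAi and Pop2 RNAi. By limma these were 3992 and 2572 with all libraries, and at most 4708 (without LacZ RNAi library C) and 3480 (without Not1 RNAi library C) with 1 left out. Men also fell 2.39-fold in Pop2 RNAi (adjusted p = 1.36e-07) in the authors' deposited table.

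Across 5847 genes Pum RNAi correlated at 0.222 with Not1 RNAi and 0.390 with Pop2 RNAi. The reconstructed reads gave 0.264 and 0.377, against 0.504 and 0.499 for simulated unchanged groups that shared a simulated control. The observed covariances were 0.152 and 0.164, against 0.0753 and 0.0741 for unchanged groups. Part of the overlap may come from the shared controls. How much cannot be told from the simulation, which did not model the LacZ RNAi library that stands apart. Shared calls by limma numbered 327 and 314 without the shallowest LacZ RNAi and Not1 RNAi libraries.

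Knockout clones 1 and 2 against WT asked which mRNAs differ when pum is mutated. Clone 1 had 2328 genes higher and 2592 lower among 10156 tested, and clone 2 had 2118 and 2333 among 9925. Both clones shared 1740 rises and 1952 falls, against 496.8 and 609.3 for independent lists, and 71 opposite calls, against 1100.4. dac, a transcription factor gene of eye and leg development, rose 27.3-fold in clone 1 and 36.4-fold in clone 2, from 8.8 to 248.6 and 331.7 normalized counts, in the authors' deposited table. The cuticle gene Cpr97Eb rose 14.2- and 13.5-fold, the lipid phosphatase gene laza 13.1- and 31.4-fold, and ptc, the Hedgehog receptor, 9.32- and 28.2-fold in the authors' deposited table. phyl (11.8- and 9.05-fold), OtopLc (8.08- and 7.60-fold), tio (7.38- and 15.9-fold) and nrv3, a sodium pump subunit (11.2- and 7.36-fold), followed in the authors' deposited table. nolo (FBgn0051619, chromosome 2L, 21684106 to 21729051) fell from 3621.3 to 5.1 in clone 1 (log2 -9.41 ± 0.33) and 52.1 in clone 2 (-6.11 ± 0.14), in the authors' deposited table. The neural adhesion gene nrm fell 93.2- and 40.7-fold, Rbp, the RIM-binding protein of synapses, 82.7- and 62.7-fold, and the integrin gene Itgbn 45.4- and 47.5-fold in the authors' deposited table. Lower still in level were the mucin gene Muc68D (134.3 in WT, listed at 0 in clone 1 and at 0.3 in clone 2), the serpin gene Spn77Ba (85.1, 0.5 and 0.9), the maltase gene Mal-B2 (73.8, 0.4 and 2.0) and the lipase gene Lip4 (72.8, 2.3 and 2.6) in the authors' deposited table.

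Ribosome biogenesis genes rose in both clones. Of 12 ribosome biogenesis genes 11 rose in each (also adjusted over the list alone; medians 1.11 and 0.93, adjusted p = 9.18e-13 and 3.00e-11, and adjusted p = 0.131 and 0.216 with an estimated correlation). On the log2 scale nop5 rose by 1.79 ± 0.09 and 1.49 ± 0.09 and Nop60B by 1.40 ± 0.06 and 1.09 ± 0.06 in the authors' deposited table. Cytosolic ribosomal protein genes had 55 higher and 5 lower of 86 in clone 1 and 73 and 1 in clone 2 (56 and 5, and 75 and 2, adjusted over the list alone; medians 0.27 and 0.47, adjusted p = 5.11e-06 and 1.56e-17, and adjusted p = 0.546 and 0.433 with an estimated correlation). RpLP0-like, a ribosome assembly factor that the list's name pattern takes in, rose 1.70 ± 0.08 and 1.20 ± 0.08, and RpL29 1.15 ± 0.12 and 1.36 ± 0.12 (log2), in the authors' deposited table. Mitochondrial ribosomal proteins had 35 and 34 of 72 higher, with 1 lower in each (36 and 35 higher adjusted over the list alone; adjusted p = 0.00293 and 0.0042, and adjusted p = 0.519 and 0.470 with an estimated correlation).

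Cell cycle genes were higher in 23 of 31 in clone 1, with 3 lower, and in 19, with 2 lower, in clone 2 (23 and 21 higher adjusted over the list alone; medians 0.57 and 0.35, adjusted p = 4.78e-07 and 7.88e-04, and adjusted p = 0.181 and 0.433 with an estimated correlation). Cdk2 rose 1.70 ± 0.11 and 1.16 ± 0.11 and the cytokinesis kinesin gene pav 1.10 ± 0.07 and 0.79 ± 0.07 (log2) in the authors' deposited table. Decay factors had 18 higher and 4 lower of 27 in clone 1 (adjusted p = 0.0353, and adjusted p = 0.131 with an estimated correlation) and 15 and 4 in clone 2 (adjusted p = 0.0808, 0.0149 by camera on the reconstructed reads, and 0.216 with an estimated correlation), the same adjusted over the list alone. LSm3 was at 1.71 ± 0.21 and 1.78 ± 0.21 and PAN3 at -0.59 ± 0.07 and -0.57 ± 0.07 (log2) in the authors' deposited table. Notch, Wnt and Hippo genes had 9 higher and 2 lower of 19, and 11 and 2 (adjusted p = 0.0353 and 0.0213, and adjusted p = 0.546 and 0.470 with an estimated correlation), with fz up 3.52- and 4.44-fold in the authors' deposited table. Ras/MAPK genes had 8 higher and 1 lower of 13, and 7 and 3 (adjusted p = 0.0129 and 0.0808, and adjusted p = 0.403 with an estimated correlation for clone 1), and Raf rose 1.60- and 1.66-fold in the authors' deposited table.

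Camera placed heat shock genes and endoplasmic reticulum and integrated stress genes lower in both clones, and glycolysis lower in clone 1. Heat shock genes had 4 lower and 2 higher of 13 in clone 1 and 6 and 1 of 12 in clone 2 (adjusted p = 0.0353 and 0.00347, adjusted p = 0.0539 in clone 1 on the reconstructed reads of 6 members, and adjusted p = 0.403 and 0.433 with an estimated correlation). The small heat shock gene Hsp23 changed by -2.75 ± 0.10 and -2.93 ± 0.10 on the log2 scale in the authors' deposited table. Endoplasmic reticulum and integrated stress genes had 8 lower and 1 higher of 11, and 7 and 0 (adjusted p = 0.00739 and 0.0147, and adjusted p = 0.289 and 0.433 with an estimated correlation), led by the chaperone gene Gp93 (log2 -0.86 ± 0.05 and -1.08 ± 0.05) in the authors' deposited table. Glycolysis enzymes were lower in 11 of 12 in clone 1 (median -0.81, adjusted p = 4.78e-07, and adjusted p = 0.279 with an estimated correlation) and in 6, with 2 higher, in clone 2 (adjusted p = 0.261), the same adjusted over the list alone. Ldh, lactate dehydrogenase, fell 6.79- and 3.33-fold, and Men, malic enzyme, 3.58- and 1.82-fold in the authors' deposited table. Germline and gonad markers had 4 lower and 2 higher of 10 in each clone (adjusted p = 0.0496 in clone 1, 0.313 there on the reconstructed reads of 7 members, 0.133 in clone 2, and adjusted p = 0.546 with an estimated correlation for clone 1). The germline Argonaute gene AGO3 fell 23.7- and 4.50-fold, while piwi rose 4.91- and 4.16-fold, in the authors' deposited table.

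The other lists did not pass camera on the deposited values in either clone. On the reconstructed reads proteasome subunits passed as lower in both (adjusted p = 0.0357 and 0.0341, and adjusted p = 0.546 and 0.514 with an estimated correlation). Higher and lower counts in clone 1, then clone 2, were 5 and 0, then 4 and 1, of 9 CCR4-NOT subunits, 3 and 2, then 2 and 1, of 11 repressors and 4 and 4, then 5 and 2, of 14 earlier reported Pumilio targets. There were 18 and 13, then 20 and 8, of 67 oxidative phosphorylation subunits, 2 and 17, then 2 and 16, of 32 proteasome subunits and 5 and 6, then 3 and 7, of 14 JAK/STAT and JNK genes. They were 3 and 4, then 2 and 4, of 13 apoptosis genes, and 2 and 6, then 3 and 5, of 14 antimicrobial genes. There were 2 and 7, then 7 and 4, of 18 glutathione transferase and oxidative stress genes, 3 and 5, then 0 and 4, of 9 RNA interference genes, 4 and 3, then 4 and 2, of 10 ecdysone genes and 3 and 3, then 0 and 5, of 12 lipid genes. Markers gave 2 and 2, then 1 and 2, of 9 for neurons, 0 and 2, then 1 and 3, of 10 for muscle and 3 and 5, then 3 and 5, of 10 for epithelium. Median, mean and camera differed in sign for the repressors, oxidative phosphorylation, ecdysone and lipid lists in clone 1 and the repressor, antimicrobial, glutathione transferase and neuron lists in clone 2. Egfr rose 0.58 ± 0.09 and 1.18 ± 0.09 and Mmp1 changed by -2.32 ± 0.10 and -2.39 ± 0.10 on the log2 scale in the authors' deposited table. Both clones share the WT libraries. Their fold changes correlated at 0.889 across genes, and on the reconstructed reads at 0.839 with a covariance of 0.922, against 0.507 and 0.0206 for unchanged groups with 0 shared calls. The 0 shared calls follow from the setting, since no gene was changed. No WT library stood apart (lowest correlation within WT 0.992). The covariance of 0.0206 against 0.922 argues against the spread of the shared WT libraries as the main source of the excess. A departure common to all WT libraries was not modelled. Only 1889 of the shared calls were at least 1.5-fold in both clones.

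**Figure D3:**
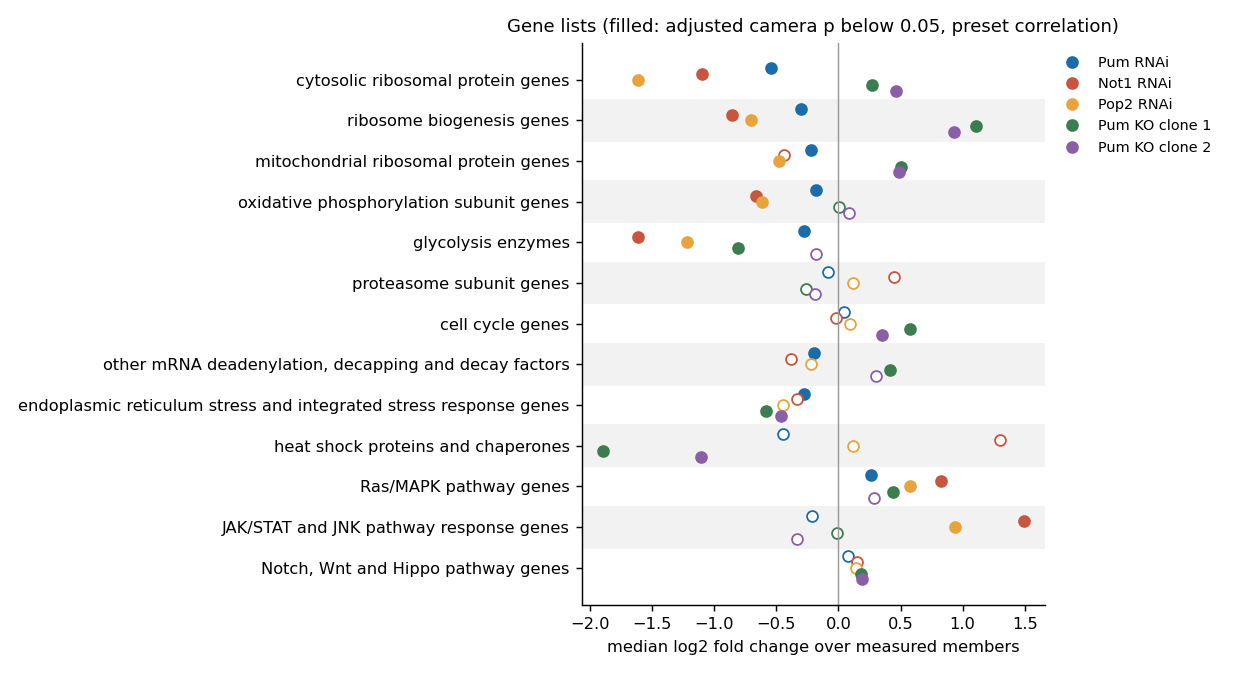
Median log2 fold change over the measured members of 13 gene lists (horizontal axis) in each of the 5 comparisons (colours), with filled points where camera with the preset correlation gave an adjusted p below 0.05. Ribosomal protein genes lie at -1.61 in Pop2 RNAi and at 0.47 in clone 2, and at -0.55 in Pum RNAi, where the median of the 44 reconstructed members was -0.38 with all libraries and 0.13 without the shallowest LacZ RNAi and Not1 RNAi libraries.

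Clones 1 and 2 also differed from each other in 730 genes by the direct test, 293 higher and 437 lower in clone 1 (1850 by limma on the reconstructed reads). Genes called in opposite directions included egr (log2 1.61 ± 0.14 in clone 1, -0.94 ± 0.17 in clone 2), the immune regulator gene pirk (-0.77 ± 0.19 and 1.25 ± 0.17), ImpL2 (-0.73 ± 0.07 and 0.40 ± 0.07) and Gad1 (0.38 ± 0.11 and -0.45 ± 0.12) in the authors' deposited table.

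Knockdown and knockout of pum were compared across the 2 tables, which have separate controls. Of the 44 genes that rose in Pum RNAi, 23 rose in both clones (8.82 for independent lists, Fisher's exact p = 1.91e-06), and of the 19 that fell 13 fell in both (4.13, Fisher's exact p = 1.67e-05), with 5 opposite calls (13.4). The shared falls include pum, the targeted gene, whose fall follows from the design. With clone 1 alone the numbers were 25 and 13, and with clone 2 alone 28 and 13. Men, PyK, klu, bib, Raf, fz and dec changed in the same direction in Pum RNAi and both clones, dec by 5.97-fold in clone 1 and 42.5-fold in clone 2 in the authors' deposited table. Over all 5847 genes the fold changes of Pum RNAi hardly correlated with those of clone 1 (r = 0.0330) and clone 2 (r = -0.00866). Without the shallowest LacZ RNAi and Not1 RNAi libraries the reconstructed reads gave r = 0.153 and 0.167 across 5628 genes, against 0.0257 and -0.00971 with all libraries. Set against the deposited calls of both clones, limma without these libraries gave 110 shared rises (64.9 for independent lists), 111 shared falls (Fisher's exact p = 3.09e-10) and 107 opposite calls (130.2 for independent lists), and with all libraries 0 shared rises and 1 shared fall.

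Many genes were called in opposite directions in the CCR4-NOT knockdowns and in both pum knockout clones. The overlaps below were not repeated without the shallowest LacZ RNAi and Not1 RNAi libraries. No unedited clone is in the design, so loss of pum and clonal isolation are not separated here. Not1 RNAi and both clones shared 312 rises and 410 falls, fewer than the 440.8 and 463.4 of independent lists, and had 1414 opposite calls, against 906. Pop2 RNAi shared 233 rises and 362 falls with both clones (325.1 and 385.2 for independent lists) and had 1132 opposite calls, against 707.8. The correlations across genes were -0.156 and -0.202 for Not1 RNAi with clones 1 and 2 and -0.101 and -0.180 for Pop2 RNAi. Nop60B, nop5 and Nopp140 fell in both CCR4-NOT knockdowns and rose in both clones, and rpr did the reverse, with a fall of 7.22-fold in clone 1 and 5.23-fold in clone 2 in the authors' deposited table.

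Along the chromosomes, the window of 1 Mb with the most extreme medians in both clones lay on chromosome 2L. The 50 genes measured at 20 to 21 Mb of chromosome 2L (dm6) had a median log2 fold change of -0.63 in clone 1 and -0.66 in clone 2, and 32 of them were called lower in both. Medians of the same genes were 0.00, 0.13 and 0.07 in Pum RNAi, Not1 RNAi and Pop2 RNAi. The adjoining window from 21 to 22 Mb (47 genes), which holds nolo and Itgbn, had medians of -0.36 and -0.25 in clones 1 and 2 and of -0.01, -0.48 and -0.30 in the knockdowns. A window on another arm, 21 to 22 Mb of chromosome 2R, lay about as far from 0 in the other direction (0.25 and 0.29).

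**Figure D4:**
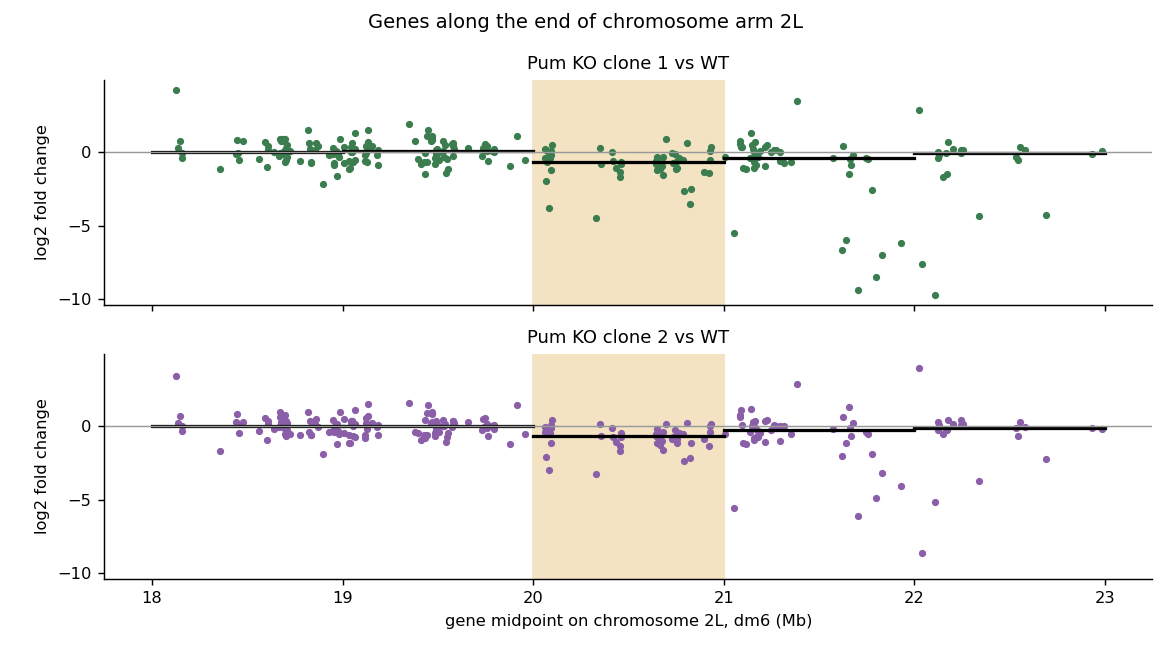
Log2 fold change against WT (vertical axis) of single genes (points) by gene midpoint along 18 to 23 Mb of chromosome 2L, dm6 (horizontal axis, Mb), for clones 1 and 2, from the authors' deposited table, with black bars at the median of each 1-Mb window. In the shaded window from 20 to 21 Mb the medians are -0.63 and -0.66, and in the next one, to 22 Mb, -0.36 and -0.25.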

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

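The comparison of the clones gene by gene was fixed before the data were examined as a test of the difference of their log2 fold changes, and the splits of the samples were run on reconstructed reads, a choice made after the tables were seen. Of 41 named genes compared, 10 had changes against WT that differed between clones 1 and 2 (fold change in clone 1 minus that in clone 2, with a Benjamini-Hochberg adjusted p). pum itself differed by -1.04 ± 0.10 (SE, adjusted p = 5.55e-23), and the 3 libraries of clone 1 (969.5 to 1073.6 normalized counts, reconstructed) all lay below the 3 of clone 2 (2086.7 to 2186.3). nolo differed by -3.30 ± 0.36 (adjusted p = 4.81e-18), nrm by -1.20 ± 0.28 (adjusted p = 5.18e-04) and AGO3 by -2.40 ± 0.20 (adjusted p = 5.12e-29), each lower in both clones and more so in clone 1. The glycolysis genes PyK and Ldh differed by -0.45 ± 0.09 (adjusted p = 1.98e-05) and -1.03 ± 0.29 (adjusted p = 0.00925), again with the larger fall in clone 1. RpLP0-like differed by 0.50 ± 0.11 (adjusted p = 2.68e-04), Nop60B by 0.31 ± 0.08 (adjusted p = 0.00279) and pav by 0.30 ± 0.10 (adjusted p = 0.0242), with the larger rise in clone 1. Gp93 differed by 0.22 ± 0.07 (adjusted p = 0.0394), with the larger fall in clone 2.

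Each comparison of 3 samples with 3 allows 10 splits, too few for a share under 0.05. With only the groups compared, limma called 2717 genes for Not1 RNAi, 2730 for Pop2 RNAi, 4955 for clone 1 and 4765 for clone 2 in the real split, and the highest of the other splits was 0 in each. The other splits put treated and control libraries on both sides, so a real difference between the groups adds to their spread. Their 0 calls thus do not measure how many genes unchanged groups would give. For Pum RNAi the real split called 0 genes by limma (629 at an unadjusted p below 0.05, and 63 in the authors' deposited table), and the highest of the others was 0.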

How the results depend on the processing

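Thresholds, the adjustment over other gene sets and the estimated correlation of gene lists were fixed before the data were examined, while the use of reconstructed reads, and with it every limma fit below, was chosen after the tables were seen. No called fold change of a named gene changed its sign in an alternative, but medians of gene lists did. In Pum RNAi those of ribosomal proteins (-0.38 by limma with all libraries, 0.13 without the shallowest LacZ RNAi and Not1 RNAi libraries), mitochondrial ribosomal proteins (-0.19 and 0.07), oxidative phosphorylation (-0.15 and 0.09) and proteasome subunits (-0.05 and 0.13) turned, among others that passed in neither setting. No paired analysis was possible because the deposited columns are group means and the reconstructed libraries carry no replicate number. Planned DESeq2 and edgeR fits (TMM, size factors and a replicate number as a block) and the search for Pumilio response elements were not run.

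The 63 genes of Pum RNAi became 28 at an adjusted p below 0.01. By limma they were 1 with all libraries, 7 and 1 with pseudocounts of 0.5 and 5, 2 without a filter, 1 with a mean of at least 20, 1 by total library size and 0 with only the groups compared. They were 1911 with library quality weights, 585 without the shallowest LacZ RNAi and Not1 RNAi libraries, and 1057 with both. Leaving out 1 library at a time gave 0 to 20, with 20 without Not1 RNAi library C and 2 without LacZ RNAi library C, the shallowest of their groups (quality weights 0.06 and 0.0618). Of the named genes of Pum RNAi, 17 were no longer called by limma with all libraries and 17 more were called without those 2 libraries. In each other comparison at most 1 named gene lost its call by limma with all libraries and the first settings (a pseudocount of 1, size factors). On simulated reads of LacZ RNAi and Pum RNAi alone, limma called 0% of genes changed 2-fold when 1 LacZ RNAi library had excess spread set by hand. It called 87% without that library and 92% with all libraries and no excess spread. The leave-one-out fits of the real reads held the other RNAi libraries as well. There, leaving out LacZ RNAi library C alone gave 2 genes, so the simulation does not account for these counts. Depth was not varied on its own, and with no excess spread 21% of genes changed 1.5-fold were called, so in this simulation most changes of that size were not detectable at this depth and number of libraries.

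The 4522 genes of Not1 RNAi were 4036 by limma with all libraries and 2717 with only the groups compared. By limma Pop2 RNAi had 2864 genes, clone 1 had 5090 and clone 2 had 4741. Leaving out 1 library gave 3735 to 4349 for Not1 RNAi, 2062 to 3732 for Pop2 RNAi (3527 in the authors' deposited table; 2062, 2094 and 2266 without Pop2 RNAi library A, B or C), 4707 to 5047 for clone 1 and 4308 to 4829 for clone 2. Pop2 RNAi had 5212 genes by limma with weights, 4816 without the shallowest LacZ RNAi and Not1 RNAi libraries and 4868 with both, and Not1 RNAi had 5267 without the 2 libraries. Requiring at least 1.5-fold left 2841, 2344 and 1889 genes for clone 1, clone 2 and both.

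The 730 genes that differed between the clones became 435 at 1.5-fold or more. By limma they were 1850, then 1837 and 1851 with the other pseudocounts, 1747 without a filter, 1727 with a mean of at least 20, 1841 by total library size, 2663 with weights, 2052 with only the groups compared and 1371 to 2097 with 1 library left out. The test on the deposited table counts the shared controls in both errors, which overstates the error by construction.

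The 115 genes that differed between Not1 RNAi and Pop2 RNAi became 63 at an adjusted p below 0.01. By limma they were 419, then 369 and 511, 335, 374 and 671 in the same order of settings, 3035 with weights, 259 with only the groups compared, 2289 without the 2 shallowest libraries, 2847 with weights as well, and 61 (without Pop2 RNAi library B) to 1238 (without LacZ RNAi library C) with 1 library left out. Between Pum RNAi and Not1 RNAi, 2994 became 3992 by limma, 5852 with weights, 5387 without the 2 libraries and 5733 with both, and 3270 to 4708 (without LacZ RNAi library C) with 1 library left out. Between Pum RNAi and Pop2 RNAi, 1670 became 1078 at an adjusted p below 0.01. By limma they were 2572, then 2530 and 2672 with the other pseudocounts, 5425 with weights, 4980 with only the groups compared, 5061 without the 2 libraries, 5464 with both, and 1744 to 3480 (without Not1 RNAi library C) with 1 left out.

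Shared calls of Pum RNAi with Not1 RNAi (33) became 15 at an adjusted p below 0.01, 0 by limma and 327 by limma without the 2 libraries. Those with Pop2 RNAi (33) became 16, 1 and 314. Those with both clones (36) became 17 at an adjusted p below 0.01, 23 at 1.5-fold or more, 1 by limma and 221 by limma without the 2 libraries, with the deposited calls of the clones in both. With an estimated correlation 0 lists were called in any comparison, with all libraries or without the 2, against 8, 6, 7, 11 and 7 for Pum RNAi, Not1 RNAi, Pop2 RNAi and clones 1 and 2. At an unadjusted p below 0.05 the numbers were 2, 3, 4, 4 and 3. Fry, which does not compare a list with other genes, called 0 (3 at an unadjusted p below 0.05), 19, 13, 22 and 23 with all libraries. Without the 2 libraries fry called the apoptosis list in Pum RNAi (fry adjusted p = 0.00816), which camera with the preset correlation did not (adjusted p = 0.520). On the reconstructed reads camera called 7 lists in Pum RNAi, and 5 without the 2 libraries. Where no construction is named, the cause was not tested.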

Other observations

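All tests of explanations in this part were chosen after the result was seen. Hemocyte markers changed in the knockout clones gene by gene, and as a list they did not pass camera in either. Of 12 hemocyte markers 4 rose and 7 fell in clone 1 (the same adjusted over the list alone; camera adjusted p = 0.0502), and 5 rose and 3 fell in clone 2 (6 and 4 adjusted over the list alone; adjusted p = 0.378). crq, a scavenger receptor gene of macrophages, fell 4.54- and 4.64-fold, He, hemese, 4.72- and 3.57-fold, and Hml, hemolectin, 10.9- and 3.77-fold in clones 1 and 2 in the authors' deposited table. vkg, a collagen IV gene, rose 6.69- and 12.8-fold (log2 2.74 ± 0.21 and 3.68 ± 0.20) in the authors' deposited table. lz, a transcription factor gene of crystal cells chosen after its values were seen, rose 85.9-fold in clone 2 (log2 6.42 ± 0.30, adjusted p = 4.88e-101), from 10.4 to 918.6 normalized counts, and fell 2.52-fold in clone 1 (log2 -1.33 ± 0.47, adjusted p = 0.0106), to 4.0, in the authors' deposited table.

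Cytosolic ribosomal protein genes were low in Pum RNAi (median -0.57 relative to all genes, 81 members with reconstructed reads). Without the shallowest LacZ RNAi library the median was 0.10 and 27.2% lay below 0, while it was -0.82 and -0.80 without either other LacZ library. Against genes nearest in length the median was still -0.50, which argues against gene length as the whole cause. A part for length is not excluded. Across 5718 genes the deviation of the shallowest LacZ RNAi library from its group ran with gene length (Spearman's rho -0.47, shorter genes higher). Library C of Pop2 RNAi had a trend of -0.56 within its own group. The 27.2% show that the low values rested on the shallowest LacZ RNAi library. They do not decide on the Pum knockdown, since these same genes stood high in that library and leaving it out had to raise their ratio. The single LacZ RNAi library is a candidate source of the low values.

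Pum RNAi and the clones barely correlated across genes (0.0232 and -0.0183 on the reconstructed reads of 5822 genes). Without the shallowest LacZ RNAi library the correlations were 0.156 and 0.169, against -0.00707 and -0.0544, and -0.0239 and -0.0748, without the others. That library may account for part of the low correlation. Changes from isolating clones, shared by both, stay open: the clones correlated with each other at 0.889, which loss of pum and clonal isolation would both give, and no unedited clone is in the design.

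Genes at 20 to 21 Mb of chromosome 2L were low in both clones (medians -0.63 and -0.66, quartiles -1.17 to -0.12 and -1.12 to -0.18). Among 10000 shuffles of genes over 116 windows none gave a median as extreme (permutation p = 1e-04, the smallest these can give), which argues against a random order of changed genes. The lowest median of the same genes in the knockdowns was 0.0014, so as a set they were not lower in any knockdown than in LacZ RNAi. LacZ RNAi cultures were bathed with double-stranded RNA too. A change common to any treated culture would thus cancel, and these values cannot decide on it. The adjoining window, from 21 to 22 Mb, was low in the clones (-0.36 and -0.25) and in Not1 RNAi and Pop2 RNAi (-0.48 and -0.30). A lower copy number shared by the clones is a candidate explanation: 40 of 50 genes (80%, against 41.5% of all genes) were below 0 in both. Copy number and regulation of the region cannot be told apart here, since no DNA was measured.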
